A study of Homo sapiens with 24 samples.

How the data were processed

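RNA sequencing libraries of 4 human lung cancer cell lines were examined, with 24 libraries in 8 groups of 3. Per the labels, total RNA was extracted with on-column DNase treatment, libraries were strand-specific, and each group held independent biological replicates. Groups were taken from the sample titles and genotype labels, which name control and overexpressing cells for A549 and H1299, and control and CRISPR cells, with a knockdown genotype, for DMS454 and H1694. Library codes in the tables were joined to the samples through the labels, and the meaning of the abbreviations in those codes was not stated.

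The authors trimmed the reads, aligned them with STAR to hg38 and analysed them with DESeq2. Versions, counter and annotation are not given in the sources used here. The deposited values per library are a signal, namely counts divided by the authors' size factors, and the deposited mean over libraries is a signal on the same scale. The deposited fold changes and their standard errors are on the log2 scale, the deposited p values (p_value) are raw and adjusted ones of DESeq2, and the deposited Wald statistic is a score. Whole reads were recovered from every library's values within 0.01, which gave the read totals per library. For A549 and H1299 the tables held 21306 and 20707 genes, without genes of very low mean, while those of DMS454 and H1694 held 60668 each.

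Levels are the deposited normalized counts. Genes with a mean of at least 10 normalized counts in 1 group were tested within each line with limma 3.58.1 (trend and robust settings) on log2(value + 1) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design written beforehand named edgeR for raw counts and this limma test for tables of normalized values only. The tables held normalized values, so limma was used. As alternatives, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom were run on the recovered reads. Directions are treated minus control as titled in the labels. The authors' fold changes in DMS454 and H1694 have the opposite sign, since they take the libraries titled control as the numerator.

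Gene lists, 35 in number, were tested with camera at a preset correlation of 0.01 where at least 5 members were measured, and again with an estimated correlation and with fry. They cover cell adhesion and the HEPACAM family, integrins, collagens, laminins, matrix glycoproteins and proteases, focal adhesion and junctions, neuroendocrine, mesenchymal and tuft cell markers, signalling responses, cell cycle, stress, lipid and immune genes, RNA quality (histone, mitochondrial and ribosomal genes), and markers of epithelium, fibroblasts, blood and endothelium. Overlaps between lines used a one-sided Fisher exact test over genes tested in both, and differences between lines a normal test of the difference of the log2 fold changes. The normal test treats the SEs as known, although each rests on 3 libraries per group. Its p values are therefore too low and its counts of differing genes too high. The Fisher test treats genes as independent units, which they are not, so its small p values overstate the evidence. No comparison was made between levels of different lines. The lists, the comparisons, the thresholds and the rule for named genes were written before the data were examined, except the count of genes in the same direction in all 4 lines.

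The named genes are HEPACAM2 and, per line, the 8 largest rises and the 8 largest falls among called genes whose libraries did not overlap and whose mean was at least 50 in the higher group, leaving out names that are only clone, antisense or pseudogene identifiers. Up to 4 called members of each described list with the largest absolute change and a mean of at least 50 were added, or up to 2 of the highest mean where none was called. Up to 8 genes shared by each pair of lines and up to 8 opposite genes across the 4 lines completed them. List examples in the text were taken from members whose call held under every alternative other than the log2 fold change threshold, which was applied to counts only, a choice made after the values were seen. Levels of XIST and of Y-linked genes were left out, and a few genes that the rule named are not reported here. Gene names and coordinates came from GENCODE release 29 (GRCh38) and a table of gene names, matched by identifier without its version. The match covered 99.5% of the identifiers in every line, and of the tested genes 89.8%, 89.7%, 86.6% and 87.4% in A549, H1299, DMS454 and H1694 had a symbol.

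Alternatives covered TMM scaling, no filter and a filter at a mean of 50, a pseudocount of 5, an absolute log2 fold change of at least 1, the replicate number as a block, the other tools named above, a correction of each library's GC trend, the removal of both H1299 libraries numbered 1, and leaving out each library in turn. Deviations from the group mean were correlated between the control and the treated library of the same number. The correlations ran from -0.54 in H1299 to 0.12 in H1694, so replicate numbers gave no strong pairing. In DMS454 every control correlated best with its own number, but weakly (0.02, 0.03 and 0.01). Sensitivity was tested on simulated data: reads of 50 genes per fold were changed in each line, and 60% to 90% of 1.5-fold rises and 96% to 100% of 2-fold rises were recovered, with 6 to 10 unchanged genes called. The simulation gave all genes of a line a common dispersion and held no deviating library, so these numbers may not hold for the real libraries. How the authors' counting treated reads shared by near-identical genes was not stated, so values for CEACAM6, CST1, KRTAP2-3, PAGE5, AKR1C1, AKR1C2, IFIT1 and HSP90AA1, and for HLA, histone and metallothionein genes, carry that limit.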

Results

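Gene expression was measured by strand-specific RNA sequencing of total RNA in 24 libraries from 4 human lung cancer cell lines. A549 and H1299 are lines of non-small cell lung cancer in which HEPACAM2 was overexpressed (OE). DMS454 and H1694 are lines of small cell lung cancer, a neuroendocrine tumour, in which the treated libraries are titled CRISPR and carry the genotype label of a HEPACAM2 knockdown. Each line had 3 control and 3 treated libraries, which made 8 groups of 3, and each line was compared with its own controls. Total reads per library were 16358270 to 29838960 in A549, 12704480 to 20332420 in H1299, 15652550 to 30241600 in DMS454 and 19682770 to 31770860 in H1694. Levels below are the deposited normalized counts as mean ± SD (n = 3), and changes are log2 fold changes of treated minus control with their SE from limma on log2(normalized count + 1). Folds were fitted on that scale, and they differ from the ratio of the means, most at low levels. The study's design text sets overexpressing and knockdown cells against controls. Its title names cell-matrix interactions, and the comparisons ask which genes, and which adhesion and matrix genes among them, differ with HEPACAM2.

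HEPACAM2, the targeted gene of the immunoglobulin superfamily (ENSG00000188175, chromosome 7, 93188586 to 93226524, minus strand, GRCh38), was nearly absent from the control libraries of A549 and H1299 and abundant in their overexpressing libraries. In A549 it was 0.367 ± 0.635 normalized counts in the controls and 6007 ± 124 with overexpression (log2 fold change 12.20, SE 0.24, adjusted p = 5.2e-14). The A549 controls held 1 HEPACAM2 read in all against 17391, a size-adjusted ratio of 19690 (95% counting interval 3534 to 777758.5). In H1299 it was 2.88 ± 0.724 in the controls and 25322 ± 1795 with overexpression (log2 fold change 12.69, SE 0.15, adjusted p = 3.6e-10), from 9 and 76382 reads, a ratio of 8693 (4579 to 19011). These intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

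In DMS454 and H1694 HEPACAM2 mRNA was higher, not lower, in the libraries labelled CRISPR. In DMS454 it was 6550 ± 124 in the libraries labelled control and 11187 ± 314 in those labelled CRISPR, 1.71-fold higher (log2 fold change 0.77, SE 0.04, adjusted p = 1.6e-07). In H1694 it was 3557 ± 127 and 10356 ± 214, 2.91-fold higher (log2 fold change 1.54, SE 0.04, adjusted p = 1.6e-12). All 3 libraries labelled CRISPR lay above all 3 labelled control in each line. The authors' deposited fold changes for HEPACAM2 were -0.77 and -1.54, with the libraries titled control as the numerator. Every direction given below for these 2 lines is labelled CRISPR minus labelled control and therefore follows higher, not lower, HEPACAM2 mRNA. If the titles of the 2 arms were exchanged, each of these directions would turn.

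**Figure D1:**
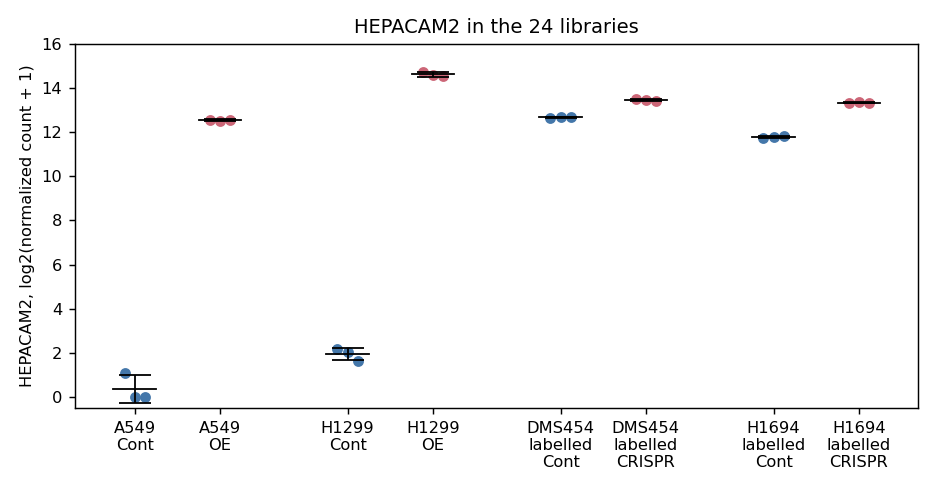
HEPACAM2 in the 24 libraries as log2(normalized count + 1), with points for libraries and lines with bars for the mean ± SD of 3 libraries on that scale. Overexpressing libraries of A549 and H1299 lie far above their controls, and in DMS454 and H1694 the libraries labelled CRISPR lie above those labelled control.

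With HEPACAM2 overexpression, A549 cells expressed more of the secreted matrix genes SPOCK1, SPARC and COL1A1 and less of the mucin gene MUC5B and the plasma protein genes FGG and CP. SPOCK1, a matrix proteoglycan (ENSG00000152377, chromosome 5, 136975298 to 137598379), rose a fitted 18.0-fold from 45.1 ± 10.9 to 815 ± 35.3 (log2 fold change 4.17, SE 0.13, adjusted p = 2.3e-19). SPARC, a collagen-binding matrix glycoprotein, rose a fitted 14.3-fold from 58.9 ± 6.96 to 849 ± 2.67, and COL1A1, a chain of type I collagen, rose a fitted 8.15-fold from 257 ± 5.62 to 2102 ± 80.2. CEACAM6, a cell adhesion molecule (ENSG00000086548, chromosome 19, 41750977 to 41772208), fell from 539 ± 37.7 to 20.2 ± 9.85 (log2 fold change -4.78, SE 0.36, adjusted p = 1.6e-04). The airway mucin MUC5B fell from 537 ± 67.4 to 49.7 ± 13.05, the fibrinogen chain FGG from 5423 ± 606 to 570 ± 171 and ceruloplasmin, CP, from 1990 ± 250 to 213 ± 38.6.

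Among the 8 largest rises in A549 were also TSPAN2 (3.38), CCBE1 (3.13), MOB3B (3.05) and FLRT2 (3.02), as log2 fold changes. The other genes among the 8 largest falls were the cystatin CST1 (-3.65), C9orf152 (-3.64), the protease inhibitor SLPI (-3.21) and ST6GALNAC1 (-3.13). Of 16707 genes tested, 3756 rose and 3661 fell at adjusted p under 0.05, 7417 in all. At least 2-fold changes were 378 rises and 586 falls. The OE and control libraries did not overlap in 51.8% of genes, against 10% by chance, and the median absolute log2 fold change was 0.21.

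Focal adhesion and actin regulators rose as a group in A549: of 57 measured members 48 rose and 6 fell, and adjusted over the list alone 48 rose and 6 fell (camera adjusted p = 2.3e-18 at the preset correlation, adjusted p = 0.153 with an estimated correlation). They included the actin-binding TAGLN (2.96), the myosin light chain MYL9 (2.79), TNS1 (2.01) and PDLIM7 (1.56). Of 26 genes of the TGF-beta response 20 rose and 3 fell (adjusted over the list alone 21 and 3, adjusted p = 3.4e-11, and adjusted p = 0.153 with an estimated correlation). The feedback inhibitor PMEPA1 (2.02) was an example. Of 26 YAP and TAZ targets 21 rose and 3 fell (adjusted over the list alone 21 and 3, adjusted p = 4.0e-11, and adjusted p = 0.199 with an estimated correlation). CCN2 (1.13), FOXF2 (0.92) and PTPN14 (0.92) were higher. Among matrix glycoproteins and proteoglycans 19 of 40 rose and 11 fell (adjusted over the list alone 19 and 12, adjusted p = 0.0037, and adjusted p = 0.153 with an estimated correlation). IGFBP7 (1.69) and TGFBI (1.41) were higher. Matrix proteases and their inhibitors moved both ways, with 17 of 33 higher and 9 lower (adjusted over the list alone 18 and 10, adjusted p = 0.0218, and adjusted p = 0.334 with an estimated correlation). The metalloproteinase ADAM19 rose (2.85), the gelatinase MMP2 rose (1.89) and MMP7 fell (-1.79). Collagens rose in 12 of 25 and fell in 7 (adjusted over the list alone 12 and 8, adjusted p = 0.0185, and adjusted p = 0.233 with an estimated correlation).

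Heat shock genes also rose in A549, with 17 of 20 higher and 1 lower (adjusted over the list alone 17 and 1, adjusted p = 4.8e-06, and adjusted p = 0.233 with an estimated correlation), by small amounts such as 0.57 for the co-chaperone CHORDC1 and 0.50 for the chaperone HSPA8. NRF2 targets, which serve oxidant defence, fell in 22 of 30 and rose in 4 (adjusted over the list alone 22 and 5, adjusted p = 3.5e-08, and adjusted p = 0.245 with an estimated correlation). The glutathione peroxidase GPX2 (-2.66) and the aldehyde dehydrogenase ALDH3A1 (-1.51) were among them. Of 38 genes of the unfolded protein and integrated stress response 25 fell and 6 rose (adjusted over the list alone 25 and 7, adjusted p = 2.6e-05, and adjusted p = 0.292 with an estimated correlation), with the transcription factor XBP1 (-1.71) and CHAC1 (-1.41) lower and the amino acid transporter SLC7A5 (1.01) higher. Genes of cholesterol and fatty acid synthesis fell in 19 of 32 and rose in 5 (adjusted over the list alone 19 and 5, adjusted p = 3.6e-05, and adjusted p = 0.279 with an estimated correlation), the sterol sensor INSIG1 (-0.58) and the regulator SREBF2 (-0.56) among them. Alveolar and airway epithelium markers fell in 9 of 15 and rose in 1 (adjusted over the list alone 9 and 1, adjusted p = 0.0015, and adjusted p = 0.153 with an estimated correlation). Among them were the mucin MUC5AC (-2.65) and the basal cell factor TP63 (-1.43).

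Smaller shifts in A549 passed the preset test for DNA replication and S phase (19 of 45 higher, 5 lower, adjusted over the list alone 21 and 5, adjusted p = 0.0216, and adjusted p = 0.441 with an estimated correlation) and for centrosome and mitosis genes (21 of 45 higher, 4 lower, adjusted over the list alone 22 and 4, adjusted p = 0.0236, and adjusted p = 0.549 with an estimated correlation). Antigen presentation genes were lower in 7 of 19 and higher in 1 (adjusted over the list alone 7 and 1, adjusted p = 0.0451, and adjusted p = 0.233 with an estimated correlation). In all, 14 of 32 tested lists passed at the preset correlation and 0 with an estimated one, where 6 had an unadjusted camera p under 0.05, while fry, which does not compare a list with other genes, called 25.

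With HEPACAM2 overexpression, H1299 cells expressed more of the gelatinase gene MMP2 and the co-receptor gene NRP1 and less of ANKRD1, a YAP target. MMP2 (ENSG00000087245, chromosome 16, 55389700 to 55506691) rose a fitted 23.5-fold from 4.54 ± 0.501 to 129 ± 11.1 (log2 fold change 4.56, SE 0.22, adjusted p = 1.2e-05). NRP1, which binds semaphorins and VEGF, rose a fitted 10.4-fold from 6.49 ± 2.54 to 75.5 ± 20.6, and the secreted protein SRPX rose a fitted 6.71-fold from 417 ± 23.7 to 2803 ± 139. BIK, a BH3-only gene of apoptosis, rose a fitted 10.2-fold from 18.4 ± 1.71 to 202 ± 52.9. ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276) fell from 1320 ± 200 to 88.3 ± 11.3 (log2 fold change -3.88, SE 0.14, adjusted p = 3.6e-06).

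Among the 8 largest rises in H1299 were also SYTL5 (3.62), SLC37A2 (2.83) and OLFML2A (2.69). The other genes among the 8 largest falls were CALHM4 (-2.95), KRTAP2-3 (-2.36), ZNF404 (-2.03), the glutamate transporter SLC1A3 (-2.02), VSTM1 (-1.95), SALL3 (-1.89) and adrenomedullin, ADM (-1.89). Of 16192 genes tested, 2181 rose and 2484 fell, 4665 in all. Of these 588 rose and 235 fell at least 2-fold, and 43.3% of all genes did not overlap between groups, against 10% by chance. The count rested on single libraries: it was 2843 without control 2, 2674 without control 3, 2865 without OE 2 and 2732 without OE 3. Control 1 and OE 1 stood apart from the other 2 libraries of their groups, and without both the count was 8922. In GC content each of them lay on the side of the other group. With the replicate number as a block it was 1634.

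Several matrix and adhesion lists rose in H1299, where control 1 and OE 1 stood apart in GC content, and 16 to 20 lists passed when any 1 library was left out. A grouping across treatment, control 1, OE 1 and OE 2 against the rest, passed 20 lists, and the real grouping passed 19. The number of list calls in H1299 thus does not set the real groups apart. Laminins and basement membrane genes rose in 12 of 20 and fell in 1 (adjusted over the list alone 14 and 1, adjusted p = 8.6e-07, and adjusted p = 0.0969 with an estimated correlation). The called members included the laminin chains LAMA4 (2.67), LAMA3 (1.45) and LAMA5 (1.34). Of 35 matrix proteases and inhibitors 18 rose and 2 fell (adjusted over the list alone 18 and 2, adjusted p = 1.8e-06, and adjusted p = 0.0835 with an estimated correlation). The serpin SERPINE2 (2.42), the collagenase MMP1 (2.25) and the crosslinking enzyme LOXL1 (2.20) were higher. Matrix glycoproteins and proteoglycans rose in 22 of 41 and fell in 4 (adjusted over the list alone 24 and 5, adjusted p = 2.1e-06, and adjusted p = 0.0835 with an estimated correlation). Examples included LTBP1 (1.94), LTBP2 (1.83) and SPARC (1.71). Integrins rose in 11 of 18 and fell in 2 (adjusted over the list alone 13 and 2, adjusted p = 1.6e-05, and adjusted p = 0.0835 with an estimated correlation). ITGB4 (2.37), ITGB8 (2.04), ITGB3 (1.91) and ITGA2 (1.83) were higher. Collagens rose in 11 of 16 and fell in 1 (adjusted over the list alone 11 and 1, adjusted p = 0.0011, and adjusted p = 0.138 with an estimated correlation). Focal adhesion and actin regulators, with 11 of 54 higher and 8 lower, did not pass (adjusted p = 0.727), nor did cadherins and junctions (adjusted p = 0.770).

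Other lists that rose in H1299 included the interferon response, with 14 of 29 higher and 0 lower (adjusted over the list alone 15 and 0, adjusted p = 1.2e-05, and adjusted p = 0.0996 with an estimated correlation). Among the called genes were the interferon-induced GBP1 (1.56), SAMD9L (1.46) and IFI6 (1.17). Neuroendocrine and small cell lung cancer markers rose in 8 of 18 and fell in 1 (adjusted over the list alone 10 and 2, adjusted p = 0.0017, and adjusted p = 0.118 with an estimated correlation). RTN1 (2.02) and the synaptic genes SNAP25 (1.56) and SYT1 (1.44) were higher. Non-neuroendocrine and mesenchymal markers rose too, in 17 of 31 with 2 lower (adjusted over the list alone 17 and 3, adjusted p = 5.6e-05, and adjusted p = 0.0835 with an estimated correlation). Fibroblast markers rose in 5 of 7 (adjusted over the list alone 5, adjusted p = 3.9e-04, and adjusted p = 0.0996 with an estimated correlation), the unfolded protein and integrated stress response in 14 of 38 with 2 lower (adjusted over the list alone 15 and 4, adjusted p = 0.0011, and adjusted p = 0.126 with an estimated correlation). The HEPACAM family and immunoglobulin-like adhesion molecules rose in 7 of 24 and fell in 2 (adjusted over the list alone 8 and 2, adjusted p = 0.0114, and adjusted p = 0.190 with an estimated correlation). The overexpressed HEPACAM2 itself is among the 7, and the list was not tested without it. The members had a mean log2 fold change of 0.80 and a median of 0.22.

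Lists that fell in H1299 were led by DNA replication and S phase, with 28 of 45 lower and 1 higher (adjusted over the list alone 32 and 1, adjusted p = 5.8e-09, and adjusted p = 0.0996 with an estimated correlation). These included the replication initiation factor MCM10 (-0.67) and the transcription factor E2F8 (-0.64). Centrosome and mitosis genes fell in 13 of 45 and rose in 2 (adjusted over the list alone 17 and 2, adjusted p = 4.7e-04, and adjusted p = 0.480 with an estimated correlation). Heat shock genes fell in 12 of 19 and rose in 1 (adjusted over the list alone 12 and 1, adjusted p = 5.6e-05, and adjusted p = 0.0996 with an estimated correlation). Called members included CHORDC1 (-1.24) and the mitochondrial chaperones HSPD1 (-0.89) and HSPE1 (-0.85). YAP and TAZ targets fell in 13 of 25 and rose in 3 (adjusted over the list alone 13 and 3, adjusted p = 1.6e-04, and adjusted p = 0.111 with an estimated correlation). NUAK2 (-1.35) and CCN2 (-0.95) were lower. Inflammatory cytokines and NF-kB targets fell in 11 of 19 and rose in 2 (adjusted over the list alone 12 and 3, adjusted p = 6.1e-04, and adjusted p = 0.118 with an estimated correlation).

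The remaining H1299 list calls depended on single libraries. Tuft cell markers rose in 3 of 8 (adjusted over the list alone 4, adjusted p = 0.0317, and adjusted p = 0.190 with an estimated correlation), with adjusted p = 0.056 without control 1 and 0.055 without OE 2. Wnt targets rose in 6 of 16 and fell in 1 (adjusted over the list alone 8 and 1, adjusted p = 0.0368, and adjusted p = 0.463 with an estimated correlation), with adjusted p = 0.12 without OE 2. Antigen presentation genes rose in 6 of 18 and fell in 1 (adjusted over the list alone 7 and 1, adjusted p = 0.0397, and adjusted p = 0.341 with an estimated correlation), with adjusted p of 0.061, 0.071, 0.062 and 0.064 without control 2, control 3, OE 2 and OE 3. Over all alternatives the adjusted p of these lists ranged from 0.0025 to 0.190, 0.0210 to 0.463 and 0.0171 to 0.341. In all, 19 of 33 tested lists passed at the preset correlation and 0 with an estimated one, where 13 had an unadjusted camera p under 0.05, while fry called 19.

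**Figure D2:**
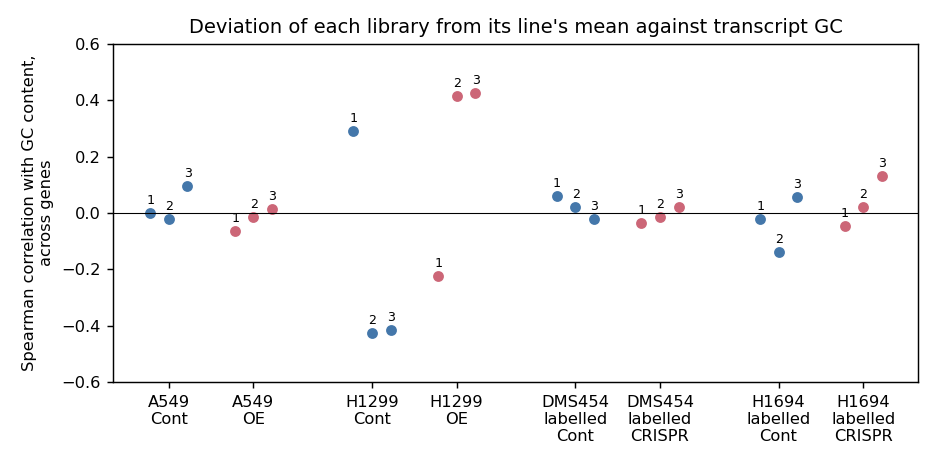
Spearman correlation, across genes, between each library's deviation from the mean of its line's 6 libraries and the GC content of the transcript, with points numbered by replicate. In H1299, control 1 (0.29) stands apart from controls 2 and 3 (-0.43 and -0.42), and OE 1 (-0.22) from OE 2 and 3 (0.42 and 0.42).

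Whether the overexpressing lines shared changes was asked over the 14578 genes tested in both, and more genes moved oppositely than together. MMP2 (1.89 in A549 and 4.56 in H1299), SPARC (3.83 and 1.71), MDGA1 (2.22 and 1.90), CPA4 (2.53 and 1.43), PMEPA1 (2.02 and 1.53), FRMD5 (1.55 and 1.72) and HIVEP3 (1.46 and 1.64) rose in both lines, and the cytokine TNFSF15 (-2.53 and -1.49) fell in both. COL1A1 differed between the lines (3.03 in A549 and -0.45 in H1299, adjusted p of the difference = 4.1e-15), as did CCN2 (1.13 and -0.95, adjusted p = 3.0e-102), XBP1 (-1.71 and 0.45, adjusted p = 1.6e-66) and HSPA8 (0.50 and -0.81, adjusted p = 8.1e-30). The genes called in the same direction numbered 428 higher (470 expected from independent lists, one-sided Fisher exact p = 0.992) and 215 lower (487 expected, p = 1), 643 in all. Another 1046 rose in A549 and fell in H1299 (560 expected, one-sided Fisher exact p = 1.4e-130) and 778 fell in A549 and rose in H1299 (408 expected, p = 3.1e-95), so that 1824 of the 2467 genes called in both, or 73.9%, were opposite. The log2 fold changes had a Spearman correlation of -0.24 and a Pearson correlation of -0.12 across genes, which are not independent replicates. The small Fisher p values overstate the evidence for the same reason. The effect differed between the lines for 6888 genes, 47.2% of those tested. The normal test behind this count and the p values of the differences is too liberal. Up to 1284 genes still passed it when the libraries of both lines were regrouped across treatment. The shared count was 372 without H1299 control 2, 356 without control 3, 357 without OE 2, 359 without OE 3, 970 after a GC correction, 223 with the replicate number as a block and 1452 without both H1299 libraries numbered 1.

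**Figure D3:**
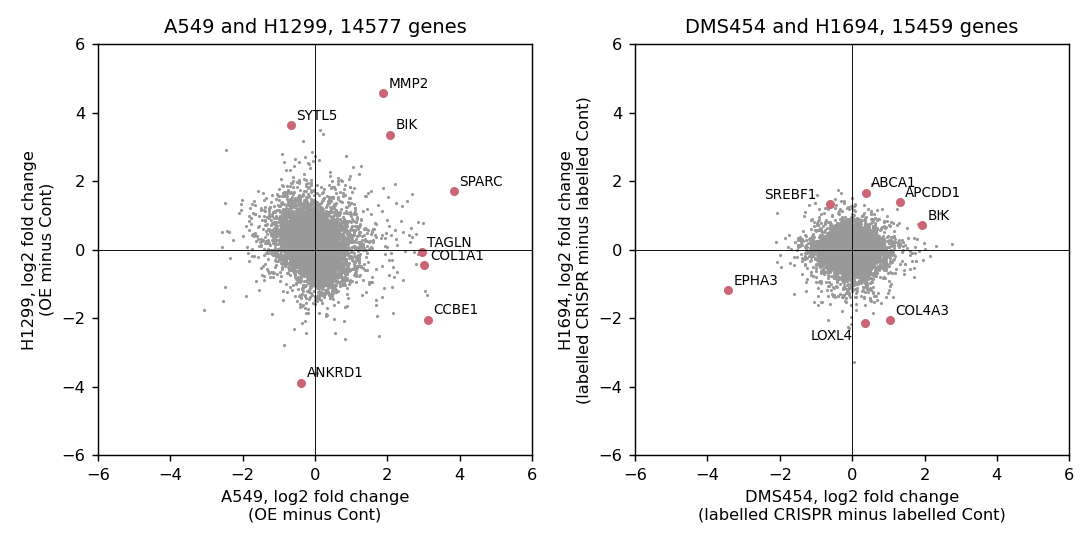
Log2 fold change per gene in one line of each pair against the other, for genes tested in both, HEPACAM2 left out, as OE minus control in A549 and H1299 and as labelled CRISPR minus labelled control in DMS454 and H1694. The Spearman correlations across genes are -0.24 and -0.05, and SPARC and MMP2 lie in the upper right of the A549 and H1299 panel.

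In DMS454 the libraries labelled CRISPR, which held more HEPACAM2 mRNA, had less of the ephrin receptor EPHA3 and of the secreted protein AZGP1 and more of BIK. EPHA3 (ENSG00000044524, chromosome 3, 89107524 to 89482134) fell from 125 ± 9.63 to 11.6 ± 5.45 (log2 fold change -3.42, SE 0.31, adjusted p = 2.0e-05), and AZGP1, a zinc-binding glycoprotein, fell from 2865 ± 224 to 817 ± 95.6. BIK rose a fitted 3.81-fold from 417 ± 8.07 to 1602 ± 199 (log2 fold change 1.93, SE 0.08, adjusted p = 4.3e-08). The apolipoprotein APOA2 (ENSG00000158874, chromosome 1, 161222292 to 161223631) rose a fitted 5.97-fold from 50.9 ± 8.15 to 334 ± 181 (log2 fold change 2.58, SE 0.34, adjusted p = 0.0027), and the tight junction gene CLDN1 rose a fitted 3.84-fold from 24.1 ± 2.43 to 95.8 ± 13.01.

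The other DMS454 genes among the 8 largest rises were PNMA3 (2.48), PAGE5 (2.18), the GTPase RIT2 (1.96), the adenylyl cyclase ADCY2 (1.86) and TRDN (1.79). The other genes among the 8 largest falls were ABHD12B (-2.11), MPZL2 (-1.95), the channel ASIC4 (-1.86), the GDNF-family receptor GFRA3 (-1.77), TCERG1L (-1.74) and MS4A8 (-1.69). PNMA3 was no longer called without control 1 (adjusted p = 0.0708), without control 3 (adjusted p = 0.0831) or without the filter on low values (adjusted p = 0.0661), in a range of 4.8e-05 to 0.0831 over the alternatives for PNMA3 in DMS454. Of 18868 genes tested, 1726 rose and 1834 fell, 3560 in all. Of these 142 rose and 205 fell at least 2-fold, and 36.6% of all genes did not overlap between groups, against 10% by chance. The count was 2203, 1964 and 1994 without controls 1, 2 and 3, 2073 and 2333 without the libraries labelled CRISPR 1 and 2, and 6605 without CRISPR 3, which stood apart from the other 2 libraries of its group.

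NRF2 targets were lower in the DMS454 libraries labelled CRISPR, with 15 of 30 lower and 1 higher (adjusted over the list alone 20 and 1, adjusted p = 4.6e-09, and adjusted p = 0.458 with an estimated correlation). Those included the epoxide hydrolase EPHX1 (-0.82) and OSGIN1 (-0.58). Genes of cholesterol and fatty acid synthesis fell in 8 of 32 and rose in 2 (adjusted over the list alone 8 and 2, adjusted p = 0.0104, and adjusted p = 0.458 with an estimated correlation), with the sterol carrier STARD4 (-1.31), the desaturase FADS2 (-1.09) and the regulator SREBF1 (-0.63) lower and ACSS2 (0.36) higher. Laminins and basement membrane genes fell in 9 of 24 and rose in 3 (adjusted over the list alone 11 and 3, adjusted p = 0.0248, and adjusted p = 0.458 with an estimated correlation), with the type IV collagen chain COL4A1 lower (-1.14) and SMOC1 higher (0.74). Neuroendocrine and small cell lung cancer markers fell in 16 of 46 and rose in 5 (adjusted over the list alone 18 and 6, adjusted p = 0.0334, and adjusted p = 0.579 with an estimated correlation), with the neuronal enolase ENO2 (-0.87) and SEZ6 (-0.76) lower and the synaptotagmin SYT4 (0.82) higher. Notch pathway genes fell in 6 of 23 and rose in 2 (adjusted over the list alone 7 and 3, adjusted p = 0.0113, and adjusted p = 0.318 with an estimated correlation), with the Notch targets NRARP (-0.64) and HEY1 (-0.56) lower and NOTCH2 (0.59) higher. Ribosomal protein genes rose in 15 of 40 and fell in 0 (adjusted over the list alone 20 and 0, adjusted p = 2.2e-06, and adjusted p = 0.579 with an estimated correlation), with RPL15 (0.79) and RPL32 (0.76) highest among them. Interferon response genes rose in 6 of 33 and fell in 2 (adjusted over the list alone 8 and 2, adjusted p = 0.0104, and adjusted p = 0.579 with an estimated correlation). The antiviral OAS1 (1.40) was higher. Without CRISPR 3 the adjusted p was 0.18 for cholesterol and fatty acid synthesis and 0.38 for neuroendocrine markers, and without control 2 it was 0.057 for laminins and 0.065 for neuroendocrine markers. Over all alternatives it ranged from 0.0019 to 0.458, 0.0091 to 0.579 and 0.0079 to 0.458 for cholesterol synthesis, neuroendocrine markers and laminins.

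Further DMS454 lists passed the preset test, again as labelled CRISPR minus labelled control. Centrosome and mitosis genes fell in 12 of 45 and rose in 2 (adjusted over the list alone 12 and 2, adjusted p = 3.7e-04, and adjusted p = 0.583 with an estimated correlation). Antigen presentation genes rose in 5 of 19 (adjusted over the list alone 7, adjusted p = 0.0031, and adjusted p = 0.318 with an estimated correlation) and inflammatory cytokines and NF-kB targets in 2 of 15 (adjusted over the list alone 2, adjusted p = 0.0113, and adjusted p = 0.318 with an estimated correlation). Histone genes fell in 2 of 12 (adjusted over the list alone 3, adjusted p = 0.0093, and adjusted p = 0.318 with an estimated correlation) and alveolar and airway epithelium markers in 5 of 12 (adjusted over the list alone 6 lower and 1 higher, adjusted p = 0.0104, and adjusted p = 0.318 with an estimated correlation). The HEPACAM family and immunoglobulin-like adhesion molecules fell in 10 of 31 and rose in 3 (adjusted over the list alone 12 and 4, adjusted p = 0.0486, and adjusted p = 0.579 with an estimated correlation), and metallothioneins fell in 1 of 8 (adjusted over the list alone 5, adjusted p = 0.0345, and adjusted p = 0.579 with an estimated correlation). Mitochondrially encoded mRNAs passed the list test as lower with 0 of 13 members called (adjusted over the list alone 0, adjusted p = 0.0334, and adjusted p = 0.667 with an estimated correlation), with MT-CO1 at -0.21 (adjusted p = 0.63) and MT-ND4 at -0.20 (adjusted p = 0.69). Their share of reads was 4.54%, 4.14% and 4.53% in the libraries labelled control and 3.66%, 2.87% and 5.05% in those labelled CRISPR. Many of these calls ended when a library was left out. Without CRISPR 3 the adjusted p was 0.12 for centrosome and mitosis, 0.064 for histone genes, 0.064 for inflammatory genes and 0.055 for metallothioneins, for which it was 0.053 without control 3 and 0.063 without CRISPR 2. Mitochondrially encoded mRNAs had adjusted p of 0.12, 0.058, 0.055 and 0.63 without control 1, control 3, CRISPR 1 and CRISPR 2. The HEPACAM family had 0.060, 0.065 and 0.053 without controls 1, 2 and 3 and 0.070 and 0.066 without CRISPR 1 and 2. Fry ended the calls of centrosome and mitosis (adjusted p = 0.146), ribosomal proteins (0.0513), interferon response (0.167), neuroendocrine markers (0.167), metallothioneins (0.0890), mitochondrially encoded mRNAs (0.492) and the HEPACAM family (0.146). The replicate number as a block and the GC correction each ended 1 of the 15 list calls of this line. In all, 15 of 33 tested lists passed at the preset correlation and 0 with an estimated one, where 5 had an unadjusted camera p under 0.05, while fry called 10.

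In H1694 the libraries labelled CRISPR, which again held more HEPACAM2 mRNA, had more of the sterol exporters ABCG1 and ABCA1 and less of the membrane protein PLPPR4, the membrane repair protein MYOF and the collagen-crosslinking enzyme LOXL4. ABCG1 rose a fitted 3.31-fold from 84.9 ± 12.03 to 282 ± 11.6, and ABCA1 (ENSG00000165029, chromosome 9, 104781002 to 104928237) rose a fitted 3.16-fold from 146 ± 5.53 to 462 ± 12.3 (log2 fold change 1.66, SE 0.09, adjusted p = 3.5e-09). PLPPR4 fell from 1252 ± 5.97 to 256 ± 15.8, MYOF from 424 ± 24.4 to 86.9 ± 3.04, and LOXL4 (ENSG00000138131, chromosome 10, 98247690 to 98268250) from 1159 ± 38.7 to 261 ± 5.92 (log2 fold change -2.15, SE 0.06, adjusted p = 3.8e-12). The cardiac myosin gene MYH6 had the highest log2 fold change of the named rises, 2.72, at a low level (12.3 ± 4.79 to 83.1 ± 15.1).

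The other H1694 genes among the 8 largest rises were PTHLH (1.65), CMTM5 (1.64), the calgranulin S100A8 (1.49), the Wnt inhibitor APCDD1 (1.38) and OLMALINC (1.35). The other genes among the 8 largest falls were the basement membrane collagen COL4A3 (-2.06), PRDM12 (-1.98), LGR6 (-1.80), CALCRL (-1.76) and the chemerin receptor CMKLR1 (-1.62). Of 17780 genes tested, 1552 rose and 1582 fell, 3134 in all. Of these 73 rose and 165 fell at least 2-fold, and 35% of all genes did not overlap between groups, against 10% by chance. The count was 1945 without control 1, 1835 without control 2 and 1896 without the library labelled CRISPR 2, and the library labelled CRISPR 1 stood apart from the other 2 of its group.

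Genes of cholesterol and fatty acid synthesis rose as a group in the H1694 libraries labelled CRISPR, with 20 of 32 higher and 0 lower (adjusted over the list alone 21 and 0, adjusted p = 5.8e-15, and adjusted p = 0.228 with an estimated correlation). The lipid regulator SREBF1 (1.32), the sterol sensor INSIG1 (0.90) and the desaturase SCD (0.81) were among them. Antigen presentation genes fell in 11 of 17 and rose in 0 (adjusted over the list alone 11 and 0, adjusted p = 1.0e-06, and adjusted p = 0.228 with an estimated correlation). Among these were the peptidase ERAP2 (-0.73), the proteasome subunit PSMB9 (-0.51) and the peptide transporter TAP1 (-0.42). Interferon response genes fell in 10 of 24 and rose in 0 (adjusted over the list alone 11 and 0, adjusted p = 1.5e-04, and adjusted p = 0.228 with an estimated correlation). PARP14 (-0.97), CMPK2 (-0.40) and STAT2 (-0.36) were lower. NRF2 targets fell in 10 of 25 and rose in 0 (adjusted over the list alone 11 lower and 1 higher, adjusted p = 2.6e-04, and adjusted p = 0.566 with an estimated correlation). The reductases AKR1B10 (-1.28) and NQO1 (-1.27) and the NRF2 target OSGIN1 (-1.19) were lower. Heat shock genes fell in 11 of 20 and rose in 0 (adjusted over the list alone 12 and 0, adjusted p = 8.4e-04, and adjusted p = 0.580 with an estimated correlation), for example the co-chaperone DNAJB1 (-0.48) and the collagen chaperone SERPINH1 (-0.44). Non-neuroendocrine and mesenchymal markers fell in 7 of 20 and rose in 1 (adjusted over the list alone 9 and 2, adjusted p = 0.0072, and adjusted p = 0.580 with an estimated correlation). MYC (-0.71) and the transcription factor SNAI2 (-0.61) were lower. Immediate early and MAPK feedback genes rose in 9 of 29 and fell in 4 (adjusted over the list alone 11 and 5, adjusted p = 0.0200, and adjusted p = 0.566 with an estimated correlation). ETV4 (1.04), the phosphatase DUSP4 (0.62) and FOS (0.59) were higher. In all, 7 of 34 tested lists passed at the preset correlation and 0 with an estimated one, where 3 had an unadjusted camera p under 0.05, while fry called 18.

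Whether DMS454 and H1694 shared changes between their labelled groups was asked over 15460 genes. EPHA3 (-3.42 in DMS454 and -1.18 in H1694), the cofactor VGLL3 (-1.60 and -1.29), FAXDC2 (-1.01 and -0.79), EYA1 (-0.99 and -0.93), BEST3 (-0.95 and -1.61), the glutamate receptor GRIN2C (-0.87 and -0.90) and WNT11 (-1.27 and -0.93) fell in both lines, and APCDD1 rose in both (1.31 and 1.38). WNT11 was no longer called in H1694 without control 2 (adjusted p = 0.0614, in a range of 4.8e-04 to 0.0614 over the alternatives for WNT11 in H1694). The lines differed in SREBF1 (-0.63 in DMS454 and 1.32 in H1694, adjusted p of the difference = 9.5e-132), COL4A3 (1.05 and -2.06, adjusted p = 8.1e-13), LOXL4 (0.36 and -2.15, adjusted p = 3.2e-57) and SYT4 (0.82 and -0.33, adjusted p = 9.5e-65). Genes called in the same direction numbered 152 higher (127 expected, one-sided Fisher exact p = 0.0101) and 198 lower (130 expected, p = 5.1e-10), 350 in all. A further 164 rose in DMS454 and fell in H1694 (132 expected, one-sided Fisher exact p = 0.0014) and 197 fell in DMS454 and rose in H1694 (126 expected, p = 4.5e-11), so that 361 of 711 genes called in both, or 50.8%, were opposite. Every combination of directions thus exceeded its expected count, so the excess was not particular to genes that moved together. The Fisher p values treat genes as independent and overstate the evidence. The Spearman correlation across genes was -0.05, and the effect differed between the lines for 4118 genes, 26.6% of those tested. The same too liberal normal test gave this count and the p values of the differences. Up to 125 genes passed it when the libraries of both lines were regrouped across treatment. The shared count was 222, 225, 231 and 635 without DMS454 control 2, control 3, CRISPR 1 and CRISPR 3, and 233 and 229 without H1694 controls 1 and 2.

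Over the 13198 genes tested in all 4 lines, 12 were called in opposite directions in the overexpression and labelled CRISPR comparisons, against 7.30 expected from independent lists, 10 of them higher with overexpression. HEPACAM2 mRNA itself was higher in the treated libraries of all 4 lines as labelled, so no gene of this set followed it in all 4. They included the chromatin remodeller SMARCA2 (0.22 in A549, 0.60 in H1299, -0.74 in DMS454 and -0.49 in H1694) and the splicing regulator MBNL2 (0.27, 0.78, -0.57 and -0.50), whose calls held in every line when any 1 library was left out. The other named genes were SHOX2 (0.94, 0.33, -0.48 and -0.57), the kinase PIM1 (0.41, 0.64, -0.23 and -0.21), TMOD2 (0.47, 0.82, -0.30 and -0.20), BTBD6 (0.31, 0.41, -0.25 and -0.38), MYL6 (0.33, 0.26, -0.28 and -0.24) and the checkpoint kinase CHEK2 (-0.58, -0.39, 0.21 and 0.21). Their calls were lost without single libraries. For MYL6 in H1299 the adjusted p was 0.0748, 0.0827 and 0.0974 without controls 1, 2 and 3 and 0.0901, 0.0778 and 0.120 without OE 1, 2 and 3. For SHOX2 in H1299 it was 0.0746, 0.0609 and 0.0533 without control 2, OE 2 and OE 3. Without control 2, control 3, OE 2 and OE 3 it was 0.137, 0.167, 0.160 and 0.144 for CHEK2 in H1299, and 0.115, 0.132, 0.130 and 0.0904 for BTBD6 in H1299. Without controls 1 and 2 it was 0.0756 and 0.0729 for PIM1 in DMS454, and without controls 2 and 3 it was 0.169 and 0.158 for BTBD6 in DMS454. For CHEK2 in DMS454 it was 0.137, 0.0713 and 0.0745 without controls 1, 2 and 3 and 0.140 and 0.0651 without CRISPR 1 and 2. For TMOD2 in H1694 it was 0.118, 0.0892 and 0.0771 without control 1, control 2 and CRISPR 3. For CHEK2 in H1694 it was 0.0751, 0.120 and 0.158 without controls 1, 2 and 3 and 0.0783, 0.0994 and 0.0793 without CRISPR 1, 2 and 3. Other settings ended calls too. With the replicate number as a block the adjusted p was 0.217 for MYL6 in H1299, 0.122 for SHOX2 in H1299, 0.0533 for TMOD2 in H1299, 0.125 for BTBD6 in H1299 and 0.161 for CHEK2 in H1299. After the GC correction it was 0.132 for BTBD6 in H1299 and 0.0751 for BTBD6 in DMS454. With DESeq2 it was 0.0675 for MYL6 in H1299, 0.0792 for CHEK2 in DMS454 and 0.143 for CHEK2 in H1694. For CHEK2 in H1299 it was 0.0510 with limma-voom, for CHEK2 in DMS454 0.0509 without the filter on low values, and for CHEK2 in H1694 0.0930 without that filter and 0.0520 with TMM scaling.

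Because HEPACAM2 mRNA was higher in the treated libraries of all 4 lines as labelled, genes called in the same direction in all 4 were also counted, a comparison and a choice of genes made after the values were seen. There were 19 such genes, 17 higher and 2 lower, against 7.26 expected, and HEPACAM2, which prompted the count, was 1 of the 17. BIK was higher in each (2.09, 3.36, 1.93 and 0.72 in A549, H1299, DMS454 and H1694), as were the TEAD cofactor VGLL4 (1.14, 1.04, 0.87 and 0.31), the phosphatase DUSP23 (1.17, 0.88, 0.32 and 0.45) and N-cadherin, CDH2 (0.88, 0.30, 0.40 and 0.21), and glutathione reductase, GSR, was lower (-0.15, -0.68, -0.44 and -0.15). The largest limma adjusted p over the lines was 0.029 for BIK (in H1694) and 0.035 for DUSP23 (in DMS454). It was 0.015 for CDH2 (in H1299) and 0.0030 for VGLL4 (in H1694). In A549 BIK reached a mean of 44.0 normalized counts, under the minimum of 50 set for named genes. Whether the calls of these genes hold in every line without single libraries is not given here. Neither the opposite genes nor those in the same direction stood out among the 8 possible sign patterns, which held 7 to 43 genes. The count of opposite genes was 4, 6, 5 and 5 without H1299 control 2, control 3, OE 2 and OE 3, 20 without DMS454 CRISPR 3 and 24 without both H1299 libraries numbered 1. The count of genes in the same direction was 10, 12, 11 and 11 without those H1299 libraries, 12 without DMS454 control 1 or H1694 control 3, and 36 without both H1299 libraries numbered 1. With the replicate number as a block the counts were 5 and 9. The count of genes in the same direction was 31 after the GC correction and 12 with DESeq2.

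Of the 35 lists, 5 passed the preset test in no line. Cadherins and junctions rose in 8 and fell in 17 of 37 in A549, 4 and 5 of 24 in H1299, 7 and 7 of 35 in DMS454 and 6 and 6 of 26 in H1694 (adjusted p = 0.151, 0.770, 0.831 and 0.840). The p53 targets rose in 10 and fell in 4 of 31, 6 and 5 of 27, 2 and 2 of 26, and 3 and 7 of 28 (adjusted p = 0.193, 0.770, 0.762 and 0.0775). Hypoxia and glycolysis genes rose in 12 and fell in 8 of 32, 5 and 6 of 29, 4 and 5 of 30, and 6 and 3 of 30 (adjusted p = 0.407, 0.930, 0.887 and 0.715). Endothelial markers could be tested in H1299 (2 of 5 higher, adjusted p = 0.110) and in H1694 (1 of 6 higher, adjusted p = 0.138), and blood cell markers had fewer than 5 measured members in every line.

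**Figure D4:**
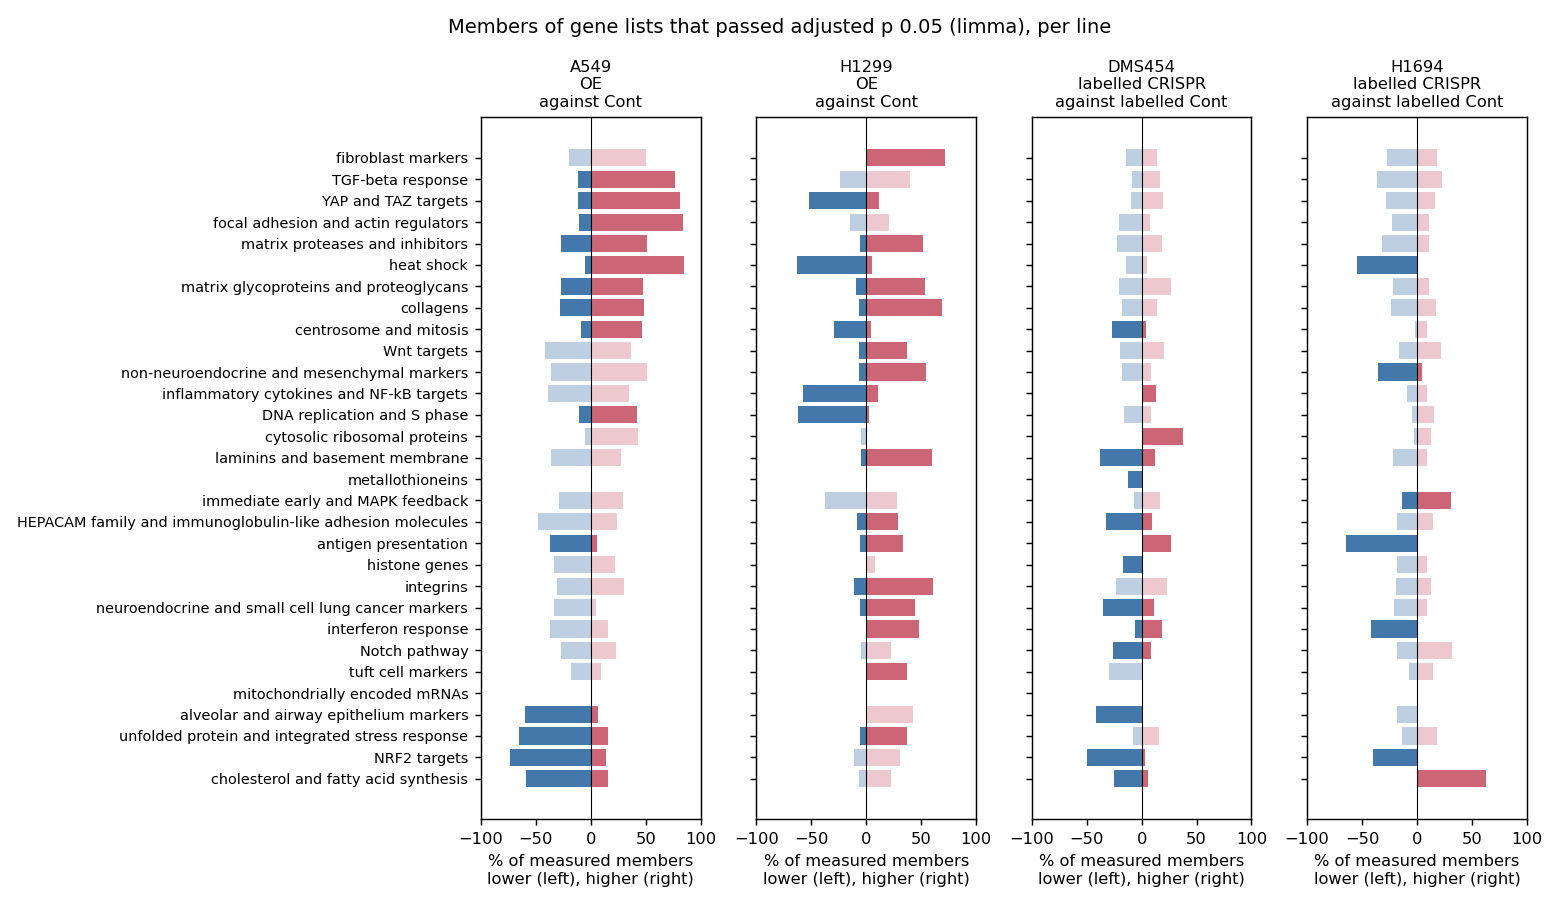
Percent of the measured members of gene lists that were higher (right) or lower (left) at adjusted p under 0.05 in each line. Changes are OE minus control or labelled CRISPR minus labelled control. Only lists that passed camera at the preset correlation in at least one of the lines are drawn. Solid bars mark lists past adjusted p 0.05 in camera at the preset correlation and faint bars the others, and lists with fewer than 5 measured members or no called member have no bar.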

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

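Tests chosen after the result was seen were those of a single wrong label, of exchanged titles, of labels exchanged in 1 line, of GC content against the correlation between lines, of a GC trend of single libraries, and the splits of libraries for the gene counts of each line.

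HEPACAM2 mRNA was higher in the libraries labelled CRISPR than in those labelled control, by log2 fold changes of 0.77 in DMS454 and 1.54 in H1694. A single library with a wrong label is argued against, since 0 of the 12 libraries lay within or beyond the range of the other group, and so are the authors' size factors, since the smaller log2 fold change with TMM scaling was 0.78. Titles of the 2 arms exchanged in both lines are a candidate explanation, since in 2 of 2 tables the deposited fold changes take the libraries titled control as the numerator. The tables of A549 and H1299 take the overexpressing libraries as the numerator. If the numerator was the treated arm in DMS454 and H1694 too, the deposited HEPACAM2 values of -0.77 and -1.54 have the sign of the labelled knockdown. In the codes of the libraries, those titled control carry G2 in DMS454 and G6 in H1694 and those titled CRISPR carry pL, which the labels do not explain, so the codes do not settle which arm was edited. An edit that leaves or raises HEPACAM2 mRNA while lowering the protein was not tested and stays open. Under exchanged titles every direction given for DMS454 and H1694 would turn.

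Fold changes in A549 and H1299 ran opposite to each other across genes (Spearman -0.24). Labels exchanged in 1 of the lines are argued against, since HEPACAM2 in the lowest overexpression library was 5332-fold that of the highest control library in the line with the smaller ratio. The correlation was -0.20 without both H1299 libraries numbered 1, which argues against those libraries as the whole cause. It was -0.24 after the GC correction, which argues against GC content as the whole cause. Without those libraries the GC trend of H1299 ran with the arms. Their removal therefore cannot argue against a technical difference between the arms. Differences between the lines in their response, and culture or handling that differed between arms within a line, may each contribute and were not tested.

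H1299 fold changes rose with GC content (Spearman 0.27 across genes, against -0.03, -0.01 and 0.04 in A549, DMS454 and H1694). The smaller within-group range of the libraries' GC correlations was 0.649 against a difference of 0.389 between the groups, and that range came from control 1 (0.29) and OE 1 (-0.22). Controls 2 and 3 (-0.43 and -0.42) and OE 2 and 3 (0.42 and 0.42) parted by group, so a trend of single libraries and a trend of the groups cannot be told apart. Control 1 lay on the side of OE 2 and 3, and OE 1 on that of controls 2 and 3. Among the other libraries the trend ran with treatment, so trend and treatment are confounded there. The GC trend as the whole cause of the H1299 calls is argued against, since 6767 genes were called after the GC correction. No biological explanation was tested.

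With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The genes called under the real and the highest other split were 7417 and 0 in A549, 4665 and 470 in H1299, 3560 and 0 in DMS454, and 3134 and 2 in H1694, where 1 split of 10 in each line, the real one, gave as many. The lists called were 14 and 9, 19 and 20, 15 and 11, and 7 and 6, where 1, 2, 1 and 1 splits gave as many. In H1299 the split that called 20 lists set control 1, OE 1 and OE 2 against the rest, so the number of list calls there does not set the real groups apart. The H1299 split that called 470 genes set controls 2 and 3 and OE 1 against the rest, which is the real grouping with control 1 and OE 1 exchanged. For pairs of lines 1 of 100 pairs of splits, the real one, gave as many differing genes. The counts were 6888 against 4309 at most otherwise (1284 with neither line in its real split) and 4118 against 2152 (125). Other splits place the treatment difference within groups and so widen the spread. The real pair was therefore favoured, and its rank does not exclude chance. For genes called in several lines the splits decided nothing. In 98, 98, 99 and 99 of the 99 other combinations a line called 0 genes, which fixed the count at 0. There 1 of 100 gave as many in each case: 643 shared genes in A549 and H1299 against 127, 350 in DMS454 and H1694 against 0, 12 opposite genes against 0, and 19 genes in the same direction against 0.

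The effect differed between A549 and H1299 for 6888 genes by the normal test of the difference, whose counts are too high. Among them were 63 of the named genes (largest adjusted p = 0.0493). As A549 minus H1299 in log2 fold change, the positive differences were CCBE1 5.18, MOB3B 4.25, VSTM1 3.67, ANKRD1 3.5, COL1A1 3.47, TAGLN 3.04, ADAM19 2.96, ZNF404 2.55, MYL9 2.33, ADM 2.19, SPARC 2.13, CCN2 2.07, NUAK2 1.82, CHORDC1 1.80, FJX1 1.71, IGFBP7 1.33, HSPA8 1.31, HSP90AA1 1.24, PDLIM7 1.10, CPA4 1.10, HSPD1 1.09, SLC7A5 1.03, PTPN14 1.02, HSPE1 1, DNAJA1 0.98, MCM10 0.91, SHOX2 0.61, MYOF 0.59, DSCC1 0.58, GINS3 0.51 and E2F8 0.42. The negative differences were SYTL5 -4.29, NRP1 -3.14, OLFML2A -2.97, SRPX -2.75, AKR1C1 -2.71, MMP2 -2.67, SNAP25 -2.56, ITGB4 -2.51, AKR1C2 -2.48, ITGB8 -2.47, CHAC1 -2.38, SYT1 -2.17, XBP1 -2.16, ITGB3 -2.14, LTBP1 -2.14, ASNS -1.81, CHGB -1.76, LAMA5 -1.49, LAMA3 -1.48, SERPINE2 -1.37, IFI6 -1.35, ITGA2 -1.34, BIK -1.27, IFIT1 -1.26, SAMD9L -1.07, TNFSF15 -1.04, SREBF2 -0.92, LTBP2 -0.87, INSIG1 -0.81, MBNL2 -0.51, SMARCA2 -0.38 and PIM1 -0.23.

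Between DMS454 and H1694 the effect differed for 4118 genes, 56 of the named ones among them (largest adjusted p = 0.0356), as labelled CRISPR minus labelled control in each line, with HEPACAM2 higher in the libraries labelled CRISPR of both. As DMS454 minus H1694, the positive differences were COL4A3 3.11, LOXL4 2.51, PLPPR4 2.20, MYOF 2.15, IFI27 2.11, ADCY2 1.90, CALCRL 1.88, SMOC1 1.34, OAS1 1.30, BIK 1.21, SYT4 1.14, NQO1 1.09, PARP14 1.01, AKR1B10 0.96, NOTCH2 0.86, ERAP2 0.85, RPL32 0.77, NEUROD1 0.75, SERPINH1 0.72, RPL15 0.68, BEST3 0.66, OSGIN1 0.61, ME1 0.60, PSMB9 0.58, TAP1 0.54, DNAJB1 0.50, MYC 0.46, TAPBP 0.46, SAMD9 0.44, CHORDC1 0.41, ACSS2 0.38, STAT2 0.37, RPL37 0.27 and RPS13 0.24. The negative differences were EPHA3 -2.24, ASIC4 -2.20, TCERG1L -2.16, ABCG1 -2.11, PTHLH -1.95, SREBF1 -1.94, GFRA3 -1.84, STARD4 -1.74, OLMALINC -1.59, FADS2 -1.36, ABCA1 -1.28, JAG2 -1.11, HEY1 -1.05, INSIG1 -1.05, NRARP -1.02, ENO2 -0.86, SCD -0.84, HEPACAM2 -0.77, SEZ6 -0.74, DUSP4 -0.68, EPHX1 -0.67 and ETV4 -0.51.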

How the results depend on the processing

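Alternatives chosen after seeing the data were edgeR, DESeq2 and limma-voom on the recovered reads, TMM scaling, the GC correction, the removal of both H1299 libraries numbered 1, and leaving out libraries for the counts across lines. The planned exchange of size factors within an edgeR fit was not run as planned, since the tables hold normalized values. The log2 fold change threshold was applied to counts only. Under every other alternative HEPACAM2 kept its direction and call, with log2 fold changes of 10.14 to 14.12 in A549, 11.65 to 13.08 in H1299, 0.75 to 0.79 in DMS454 and 1.52 to 1.57 in H1694. Of the named genes 58 of 58, 55 of 63, 47 of 58 and 51 of 56 kept their call under every alternative but that threshold in A549, H1299, DMS454 and H1694, and 0 turned direction. At this depth 1.5-fold changes were recovered in the self-test for 90%, 60%, 84% and 78% of genes in A549, H1299, DMS454 and H1694, so that smaller changes can be missed. The self-test used a common dispersion per line and no deviating library, so recovery in the real libraries may differ. Without 1 library a group held 2, and limma pooled the spread.

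With an absolute log2 fold change of at least 1, a stricter threshold, the called genes numbered 964, 823, 347 and 238, the shared genes 33 and 6, the opposite genes 0 and those in the same direction in all 4 lines 0. A log2 difference of at least 1 left 1674 and 521 differing genes. With an estimated correlation 0, 0, 0 and 0 lists were called by camera (6, 13, 5 and 3 at an unadjusted p under 0.05). Fry called 25 lists in A549 and 18 in H1694, and the GC correction gave 11 lists in H1694, 970 shared genes in A549 and H1299 and 31 genes in the same direction in all 4 lines. DESeq2 gave 12 of the latter. For fry, the GC correction and DESeq2 the cause was not tested.

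With the replicate number as a block, H1299 had 1634 called genes and A549 and H1299 shared 223. There 5 genes were opposite and 9 were in the same direction in all 4 lines. In H1299 the deviations of same-number libraries ran opposite (correlations -0.54, -0.18 and -0.31), and the cause was not tested. Without both H1299 libraries numbered 1 these counts were 8922 (4522 of them among the 4665), 1452, 24 and 36; the cause was not tested.

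Leaving out 1 library, which leaves fewer samples, gave 2674 (without control 3) to 5429 (without control 1) called genes in H1299, 1964 (without control 2) to 6605 (without CRISPR 3) in DMS454 and 1835 (without control 2) to 4510 (without CRISPR 1) in H1694. The shared genes ranged from 356 (without H1299 control 3) to 760 (without H1299 control 1) for A549 and H1299, and from 222 (without DMS454 control 2) to 635 (without DMS454 CRISPR 3) for DMS454 and H1694. Opposite genes ranged from 4 (without H1299 control 2) to 20 (without DMS454 CRISPR 3), and genes in the same direction in all 4 lines from 10 (without H1299 control 2) to 27 (without DMS454 CRISPR 3). The cause of the rises was not tested.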

Other observations

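The tests of LXR targets and of acute phase genes were chosen after the result was seen, and the genes in this part were chosen after their values were seen.

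In A549 the fibrinogen chains FGA (-2.55), FGB (-2.99) and FGG (-3.29), their relative FGL1 (-2.67), ceruloplasmin, CP (-3.23), APOH (-1.90) and complement C3 (-0.88) fell with HEPACAM2 overexpression. In DMS454, in the libraries labelled CRISPR, which held more HEPACAM2 mRNA, FGA (0.72), FGB (1.47), FGL1 (2.59), APOA1 (1.44), APOH (0.93), AHSG (1.24) and SERPINA1 (0.35) rose. Of these, FGL1 (3.30 ± 2.03 to 23.6 ± 6.54) and AHSG (10.1 ± 3.56 to 24.7 ± 4.12) were at low levels. FGL1 reached the filter mean of 10 only in the libraries labelled CRISPR. In DMS454 FGG (-0.02, limma adjusted p = 0.98), CP (0.30, adjusted p = 0.56) and TF (0.28, adjusted p = 0.50) were not called. The sterol exporters ABCA1 (1.66) and ABCG1 (1.73) and the lipid regulators SREBF1 (1.32) and SCD (0.81), targets of the LXR receptors, rose in the H1694 libraries labelled CRISPR, as did APOE (0.39). In H1299 ABCA1 (1.43), SREBF1 (0.94), PLTP (0.79) and SCD (0.79) rose with overexpression. In A549 7 of 12 measured members of the LXR list fell and 2 rose. ABCG1 (-1.40), MYLIP (-0.81), PLTP (-0.59), SCD (-0.46) and SREBF1 (-0.45) were lower, and ABCA1 (0.69) and ABCC1 (0.14) were higher. ABCC1 is also on the list of NRF2 targets, and the LXR list was not tested without it in any line. In H1694 the receptors NOTCH3 (1.30) and NOTCH1 (0.66) and the target HES1 (0.74) rose and HEY2 (-0.98) fell, while the Notch pathway list did not pass (adjusted p = 0.0861).

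Acute phase and liver secretory genes as a group may be lower with overexpression in A549: over the members other than those that prompted the list, 5 of 5 fell (7 of 7 over all members) with a median log2 fold change of -2.55, and the adjusted camera p was 3.0e-10 at the preset correlation and 0.0854 with an estimated correlation. LXR targets as a group may be higher in the H1694 libraries labelled CRISPR: over the 10 other members 3 rose and 1 fell, with a median of 0.09 and an adjusted p of 0.126 preset and 0.199 estimated. The first hypothesis passed only at the preset correlation and the second at neither. In the other lines the adjusted p of LXR targets was 0.0578 preset and 0.199 estimated in A549, 7.2e-04 and 0.0854 in H1299, where 6 of the 9 other members rose and 0 fell, and 0.751 and 0.817 in DMS454. That of acute phase genes in DMS454, where 7 of the 8 other members rose (7 of 10 over all members), was 5.3e-07 and 0.0902. The risers there included FGL1 and AHSG, both at low levels. Before the prompting genes were dropped, both tests had been run over all members with an estimated correlation, with unadjusted p of 0.0275 and 0.0276, and the adjustment covered 6 tests.

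Whether neighbouring genes moved together was not tested, and the pairs here were picked by eye. SYTL5 (3.62; chromosome X, 38006582 to 38128819) and SRPX (2.75; chromosome X, 38149336 to 38220924) rose in H1299, and MYH6 (2.72; chromosome 14, 23381990 to 23408277) and CMTM5 (1.64; chromosome 14, 23376773 to 23379772) rose in the H1694 libraries labelled CRISPR. On chromosome 7 SAMD9L lies between SAMD9 and HEPACAM2. SAMD9L had log2 fold changes of 0.40 in A549 (adjusted p = 0.178), 1.46 in H1299 (adjusted p = 7.0e-04) and -0.23 in DMS454 (adjusted p = 0.370), and in H1694 it was not tested. SAMD9 had log2 fold changes of 0.37 in A549 (adjusted p = 0.0049), 0.36 in H1299 (adjusted p = 0.0482), 0.11 in DMS454 (adjusted p = 0.578) and -0.33 in H1694 (adjusted p = 0.0214). The call of SAMD9 in H1694 was lost without control 1 (adjusted p = 0.0830), control 2 (0.121), CRISPR 2 (0.0765) or CRISPR 3 (0.0648), and with DESeq2 (0.0555). The cell cycle inhibitor CDKN1A fell in the H1694 libraries labelled CRISPR (-1.39), while the p53 target list did not pass in that line (adjusted p = 0.0775).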
